A study of Sinorhizobium meliloti 1021 with 6 samples.

How the data were processed

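RNA sequencing was analysed from symbiosomes, the membrane-bound compartments in which rhizobia live inside legume nodule cells. They were isolated from nodules of Medicago grown with Sinorhizobium meliloti Rm1021 carrying nifH::GUS for 12 days, per the labels' protocols. The 6 libraries fell into 2 groups of 3 by the host named in the labels, wild type or the debino1 mutant. Per the labels' protocols, ribosomal RNA was removed from total RNA with probes and the libraries were strand-specific. No label says whether the 3 samples of a group came from separate plants or cultures, so p-values measure only the spread between these samples, which may be technical.

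The values are RPKM, read numbers scaled by gene length and by library total, computed and deposited by the authors in a table of 6314 genes with 1 column per library. Per the submitters' processing notes CASAVA was used, with no version. The aligner, the counting program, its use of strand, its treatment of reads that match several genes, the genome build and the annotation are not given in the sources used here. All 6 columns of values were used.

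RPKM of whole reads with 6 significant digits are whole multiples of a step set by gene length and by the number of reads that the library was divided by. Both were recovered from the values by searching lengths from 20 to 11999 bp, with a rounding error of up to 0.3 reads accepted. For each of the 6 libraries the whole number nearest to the middle of the bounds lay inside them and was taken as the denominator. A length was recovered for 6201 of the 6209 genes with a value above 0 (99.9%), and 97.8% of the lengths were multiples of 3, so they are coding lengths for most genes. The 8 genes without a length were highly abundant, with mean RPKM of at least 7739. The remaining 105 genes were listed at 0 in every library. In data simulated from the debino1 and wild-type libraries, all 6 denominators came out exactly, and the reads of 6128 of 6193 genes (99.0%) did.

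The RPKM denominators were 7720265, 6859975 and 7247913 reads in wild-type replicates 1 to 3 and 5359214, 9138261 and 6165018 in debino1 replicates 1 to 3. What they count is not given in the sources used here. Reads in genes with a recovered length came to 56.8% to 57.6% of the denominator in wild type and 59.9% to 60.7% in debino1. The highly abundant genes without a length are not in this share. In a gene of 1 kb, 1 read was worth 0.109 to 0.187 RPKM. There 3 reads, an approximate upper limit on the expected number where 0 are counted, were worth 0.328 to 0.560 RPKM. These limits cover counting error only. Replicates were compared by a chi-square statistic on the recovered reads, divided by its degrees of freedom. It was 1.99 to 12.0 for pairs within the wild-type group, 2.09 to 4.62 within debino1 and 31.1 to 57.0 between groups, so no pair agreed within sampling noise, as 1 library deposited under 2 labels would. This does not show whether the libraries of a group came from separate plants or cultures.

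The comparison of debino1 with wild-type hosts was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a mean-variance trend) on log2(RPKM + 1). Fold changes on this scale understate the change of low genes. Genes with a mean of at least 1 RPKM over the 6 libraries were tested two-sided, with Benjamini-Hochberg adjustment over the 6152 genes tested and a threshold of 0.05. No count model was used for this comparison, because RPKM are not counts; voom on the recovered reads was run as an alternative. The fit was tested on simulated reads for debino1 against wild type over 6148 genes, with 50 genes changed at each fold. It called 28% of genes changed 1.25-fold, 80% at 1.5-fold, 98% at 2-fold and 100% at 4-fold, and 7 of 5948 unchanged genes. The simulation gave every gene the same replicate dispersion (0.0032) and held no library that deviated from its group. Changed genes were drawn above a minimum read number and in random directions. These rates need not hold in the real libraries, where wild-type replicate 3 differed from the other wild-type replicates. The recovery and the plots used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. MASS 7.3.60.0.1 gave the robust line used for the background estimate.

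Before the data were examined, the test, its alternatives, 26 gene lists and the rule for named genes were fixed. The gene table used here as a reference belongs to another species of the genus, Ensifer adhaerens (assembly ASM69796v2, 6946 genes). It matched 0 of the identifiers, and the files do not pair identifiers with gene names. The gene list tests, the replicon tests, the nitrogenase share and the genes chosen by name or list were therefore not analysed here, and no name was assigned from an identifier, a length or a position. Of the rule for named genes, the part that could be applied takes the 8 largest rises and 8 largest falls in limma log2 fold change. They are taken among genes past the threshold, with the same direction in every pair of a wild-type and a debino1 library, and a mean of at least 10 RPKM in the higher group. Because no names were paired, 2 identifiers are printed per direction.

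Alternatives were 2 other pseudocounts, 2 other filters on low values, 3 other scalings, 3 changes to the variance model or weights, a replicate block and leaving out each library in turn. Added after the data were seen were leaving out an abundant run of genes or 4 genes of shared lengths and rescaling the rest, the rescaling of the abundant run setting alone, voom on the recovered reads, and subtraction of an even background from 1 library. Tests on runs of genes were also chosen after the data were seen. They use the order of the identifiers in the table, which was not checked against a genome. A single value per library was compared by an exact two-sided permutation test, which with 3 against 3 cannot go below p = 0.1.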

Results

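The transcriptome of Sinorhizobium meliloti, the nitrogen-fixing partner of Medicago, was measured by RNA sequencing of symbiosomes from nodules of wild-type plants (3 libraries) and of plants with the debino1 mutation (3 libraries). The RPKM denominators of the libraries were 5359214 to 9138261 reads, and what they count is not given in the sources used here. Of the 6314 genes in the table, 6209 had a value above 0 in at least 1 library. Genes are given by their identifiers, since the files do not pair them with names. The comparison asked how bacterial gene expression in symbiosome preparations differed between debino1 and wild-type hosts. Such preparations could also hold rhizobia that have not differentiated, and the gene lists planned as their markers could not be used. A different mix of bacteria therefore cannot be told apart from changed expression.

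Bacteria from debino1 hosts differed from those in wild-type hosts at 1966 of the 6152 genes tested (32.0%). Transcript levels of 1399 genes were higher in debino1 and those of 567 genes were lower. Most changes were small: the median size among called genes was 0.45 on the log2 scale, and 105 genes rose and 30 fell by at least 2-fold. The count of 105 ranged from 67 to 159 over the alternatives tried. The count of 30 was 51 without wild-type replicate 2 and ranged from 17 to 62 over the same alternatives. The largest rise was 7.98-fold, whereas 4 genes fell by between 16.3-fold and 194-fold, to near loss in debino1. After these 4, the next fall in limma log2 fold change under the rule for named genes was only 3.16-fold, smaller than the largest rise. The lengths of these 4 genes are close to those of ribosomal RNA genes of a related species. Ribosomal RNA left by the probe depletion is therefore a candidate explanation of these 4 falls. The 4 genes held 0.354% to 0.809% of the denominator reads in the wild-type libraries and 0.0028% to 0.0043% in the debino1 libraries. If they are ribosomal RNA, its removal or the preparation may have differed between the groups. Such a difference could not be told apart from the host in any comparison here.

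**Figure D1:**
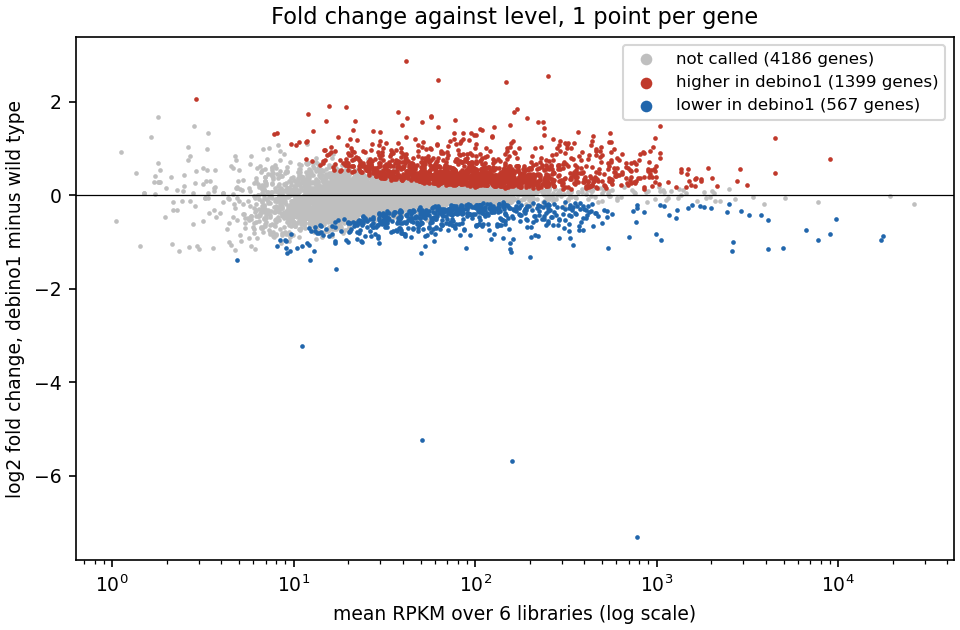
Log2 fold change (debino1 minus wild type, limma on log2(RPKM + 1)) against mean RPKM over the 6 libraries on a log axis, 1 point per tested gene. Red points are the 1399 genes called higher, blue points the 567 called lower and grey points the 4186 not called, and 4 blue points lie far below the rest.

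The excess of rises differed between scalings of the libraries. With RPKM as deposited, 71.2% of the called genes were higher in debino1, and with each library rescaled to the same sum 68.2% were (1296 higher, 604 lower). With the libraries centred on their median ratio this share was 55.6% (945 higher, 755 lower), and with quantile normalization it was 50.8% (976 higher, 947 lower). Groups did not overlap for 1386 of the 1399 rises and 558 of the 567 falls. Over all tested genes 45.1% had groups that did not overlap, where 10% is given by chance for 3 against 3.

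The largest rise was that of gene-SM2011_RS11720, a gene of 963 bp. Its RPKM was 9.27 ± 1.65 (SD, n = 3) in wild-type hosts and 74.1 ± 5.55 (SD, n = 3) in debino1 hosts, 7.98-fold higher. The recovered reads were 63, 54 and 78 in the wild-type libraries and 413, 643 and 410 in the debino1 libraries. The limma log2 fold change was 2.88 (SE 0.16, adjusted p = 1.74e-07). The next largest rise, in gene-SM2011_RS12840 of 435 bp, was from 73.3 ± 11.6 RPKM to 427 ± 18.9 RPKM (SD, n = 3 each). This was 5.82-fold, with a limma log2 fold change of 2.54 (SE 0.10, adjusted p = 1.66e-08). Both genes were higher in every debino1 library than in any wild-type library, which the rule for named genes requires.

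The largest fall was that of gene-SM2011_RS29495, with a recovered length of 2859 bp. It fell from 1544 ± 875 RPKM in wild-type hosts to 7.95 ± 1.48 RPKM in debino1 hosts (SD, n = 3 each), 194-fold lower. The reads behind these values were 24290, 19213 and 52867 in wild type against 141, 165 and 147 in debino1. The limma log2 fold change was -7.31 (SE 0.28, adjusted p = 1.66e-08). The SE was 0.39 with robust eBayes (adjusted p = 6.12e-05) and 0.77 with voom on the recovered reads (adjusted p = 4.75e-05). Without wild-type replicate 3 the fall in mean RPKM was 131-fold. The next largest fall in limma log2 fold change, though not in the ratio of mean RPKM, was that of gene-SM2011_RS29510 of 1485 bp. This gene fell from 315 ± 127 RPKM to 4.84 ± 1.38 RPKM (SD, n = 3 each). It was 65.2-fold lower, with a limma log2 fold change of -5.69 (SE 0.27, adjusted p = 6.43e-08).

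Wild-type replicate 3 had the highest wild-type value of gene-SM2011_RS29495 and the lowest of gene-SM2011_RS29510, and both stayed far above every debino1 library. A further pair of genes with the same lengths, 2859 and 1485 bp, fell 74.2-fold and 16.3-fold. Without wild-type replicate 3 the first of these falls was 44.8-fold. Genes of these lengths were followed only where at least 2 of the rows within 2 places were listed at 0 in every library. Other genes of these lengths, if any, were not examined. The remaining pair chosen in this way lay below a mean of 1 RPKM and was not tested. How reads were divided between genes of like sequence is not given in the sources used here, so the split of the falls among these genes is uncertain. Both lengths lie within 2.25% of ribosomal RNA gene lengths of a related species, so these genes may be leftover ribosomal RNA.

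**Figure D2:**
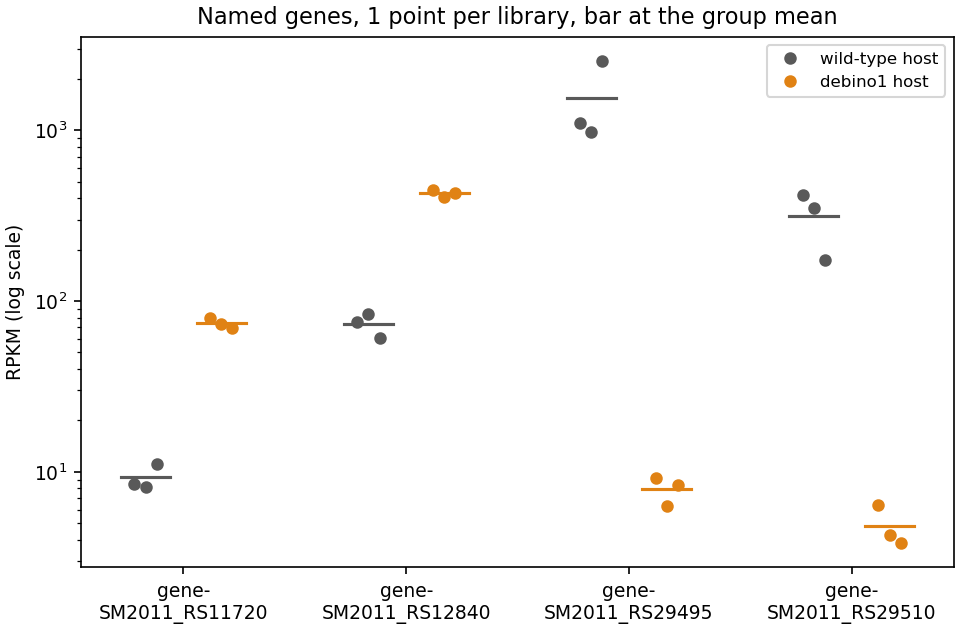
RPKM on a log axis of the 2 genes with the largest rises (left) and the 2 with the largest falls (right), ranked by limma log2 fold change. There is 1 point per library and a bar at the mean of each group of 3. Grey points are wild-type hosts and orange points debino1 hosts. The groups are apart for all 4 genes, which the rule for named genes requires.

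Among the 20 genes with the highest mean RPKM, 11 were lower in debino1, 3 were higher and 6 did not pass the test, with a median log2 fold change of -0.42. These 20 genes held 25.5% to 26.6% of the summed RPKM in the wild-type libraries and 19.4% to 20.3% in the debino1 libraries. Among the 100 most abundant genes 42 were higher and 28 lower, with a median of 0.08, and of the 82 genes at 1000 RPKM or more 27 were higher and 27 lower, with a median of -0.03. At 100 to 1000 RPKM 649 of 1246 genes (52.1%) were higher and 212 (17.0%) lower, with a median of 0.20. Genes at 30 to 100 RPKM were called higher in 597 and lower in 236 of 2334 cases. Few genes were called at low levels, with 122 higher and 83 lower of 2064 at 10 to 30 RPKM and 4 higher and 9 lower of 426 at 1 to 10 RPKM. In these low classes wild-type replicate 3 lay above the other wild-type libraries: at 5 to 10 RPKM its median excess over their mean was 4.34 RPKM.

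Of the 20 most abundant genes, 9 lay in 1 run of 13 consecutive genes, the longest in the table with mean RPKM of at least 1000 throughout. This run was chosen after its values were seen. In debino1, 10 of its genes were lower, 1 was higher and 2 did not pass the test, and the median log2 fold change was -0.88. With quantile normalization 8 were lower and 2 higher, and with median centring 10 were lower and none was called higher. The falls of 9 genes were at least 1.5-fold and those of 3 at least 2-fold.

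The share of summed RPKM in this run was 15.9% ± 0.17 (SD, n = 3) in wild-type hosts and 9.15% ± 0.28 (SD, n = 3) in debino1 hosts. The difference of -6.78 percentage points was far larger than the spread in either group. The exact two-sided permutation test gave p = 0.1, the smallest that 3 against 3 allows. With the run left out and the rest rescaled, an alternative added after the data were seen, 886 genes were higher and 918 lower. The same rescaling with no gene left out gave 885 higher and 936 lower.

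**Figure D3:**
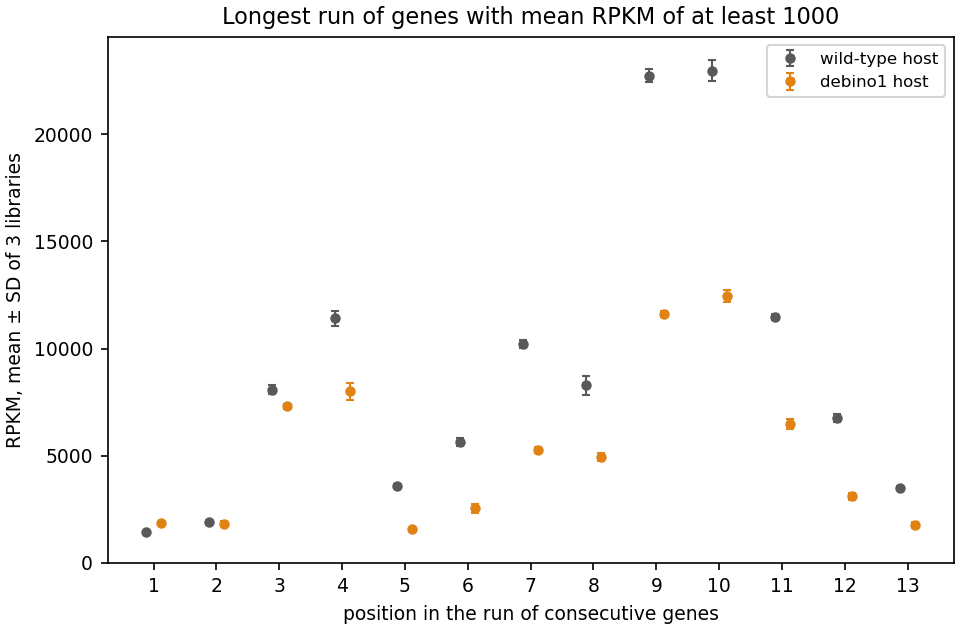
RPKM (mean ± SD of 3 libraries per group) of the 13 consecutive genes of the abundant run, by position, on a linear axis from 0. Grey points are wild-type hosts and orange points debino1 hosts, and 10 of the genes were called lower in debino1.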

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

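The abundant-run, shared-length, voom and background alternatives were chosen after the data were seen. The count of genes higher in debino1 (1399) stayed within 1.5 times in 20 of 22 alternatives, and that of genes lower (567) in 19. Quantile normalization gave 976 higher and 947 lower. Leaving out the abundant run and rescaling the rest gave 886 higher and 918 lower, with the median log2 fold change moved from 0.05 to -0.07; the rescaling alone gave 885 and 936. Subtracting an even background from wild-type replicate 3 gave 1620 and 402, with the median at 0.18. Beyond what each construction fixes, the cause was not tested. Without 1 library the counts were 1123 to 1539 higher and 426 to 545 lower, and 990 rises and 365 falls were called in all 6 such fits. Genes at least 2-fold lower (30) numbered 17 with a pseudocount of 5, 50 with median centring, 51 without wild-type replicate 2, 55 with the run left out and rescaling, 62 with that rescaling alone and 18 with the background subtracted. Genes at least 2-fold higher (105) numbered 67 with that rescaling, with or without the run, and 159 with the background subtracted. The 4 named genes kept their direction and call in every alternative that tested them, from 2.47 to 3.39 for gene-SM2011_RS11720, 2.39 to 2.64 for gene-SM2011_RS12840, -7.56 to -6.77 for gene-SM2011_RS29495 and -6.14 to -4.94 for gene-SM2011_RS29510. Without 1 library the difference in the run's share was -6.91 to -6.63 points.

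With the replicate block the counts were 1392 higher and 587 lower, of which 1347 and 531 were shared with the unblocked fit. The correlations of same-numbered deviations were -0.07, 0.21 and 0.09 across genes, and 1 of the 3 wild-type samples correlated best with its own number, so the numbers were not taken to pair the samples. Leaving out the nitrogenase list, leaving out ribosomal and transfer RNA genes, and all alternatives of the gene list, replicon and nitrogenase results were not run, because no identifier was paired with a name. At 1 to 10 RPKM 413 of 426 genes were not called, and depth was not tested as the reason.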

Other observations

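All tests in this part were chosen after the data were seen, except the splits of the libraries and the count without wild-type replicate 3.

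Genes next to each other in identifier order changed together. Across 6148 genes, which are not independent replicates, the correlation of log2 fold changes between consecutive rows was 0.46. In 10000 shuffles within 20 classes of abundance its mean was 0.05 and its highest value 0.10 (permutation p = 1e-04, the smallest these shuffles can give). There were 115 runs of at least 4 consecutive genes called in the same direction, against a mean of 38.2 and a highest of 61 after shuffling (permutation p = 1e-04, again the smallest). Of these runs 84 were rises and 31 falls.

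The longest run comprised 42 consecutive genes, all higher in debino1, with a median log2 fold change of 0.83 and a mean level of 542 RPKM. The longest after shuffling had 20. All 42 stayed above 0 with median centring, quantile normalization and the abundant run left out, and 38, 37 and 39 of them were called there. The longest run of falls had 11 genes. It lay at 7499 RPKM on average and overlapped the abundant run of the report, with a median of -0.96.

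The real split of the 6 libraries gave 1399 genes higher and 567 lower, and the highest count in either direction among the other splits was 0. In each direction, 1 of the 10 splits gave as many, the real one, and with 10 splits the share cannot go under 0.1. Every other split mixed libraries of both hosts within a group, so a difference between hosts widened the spread there. The counts of 0 therefore tell nothing on their own about the real split.

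The first pattern is the near loss of 4 genes in debino1. These falls do not come from a shift of the whole scale of the deposited RPKM, since the median log2 fold change of all other genes was 0.053. Division by the library total largely sets this median, so it tells nothing about total bacterial RNA. Ribosomal RNA left over by the probe depletion is a candidate explanation. The length of 1485 bp equals a ribosomal RNA gene length of the related species, and that of 2859 bp differs by 2.25% from the nearest. A further pair of genes with these lengths, also near genes listed at 0, lay below a mean of 1 RPKM and was not tested. Of these genes, 3 varied more among wild-type replicates than each of 200 genes of like abundance, and the other more than 90% of such genes, which did not meet the bound set for this test. Without names in the files this cannot be told apart from a change in the bacteria that follows the host genotype, which was not tested.

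The second pattern is that wild-type replicate 3 lay higher than replicates 1 and 2 at low-abundance genes, in 89.5% of genes at 5 to 10 RPKM. Lower depth is excluded, since its denominator of 7247913 reads lay between those of the other wild-type libraries. An even background of reads over genes stays open: the median excess was 5.47 RPKM at 20 to 40 RPKM and 4.34 at 5 to 10, a ratio of 1.26, but only 2.19 (quartiles 0.11 and 4.40) at 2 to 5. A robust line with a background of 7.96 RPKM and a slope of 0.906 predicts an excess of 7.58 at 2 to 5 RPKM, outside those quartiles, and lies inside the quartiles in the other 6 of 7 classes, including -1.58 observed at 80 to 160 and -17.9 at 160 to 1000. No biological explanation was tested, as the difference lies within a group.

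The third pattern is that more genes rose than fell. Background reads in wild-type replicate 3 are excluded as its cause, since without that library rises made up 74.7% of calls. With the abundant run left out and the rest rescaled, rises made up 49.1% of calls. Applying the same factors to every gene with none left out gave 48.6%, so the rescaling itself sets this value, and whether the excess comes from loss of the run from a fixed total cannot be told apart from another shift of that size. Whether total bacterial RNA differed between hosts was not measured, and a change with the host genotype stays open.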
